A study of Mus musculus with 2 samples.

How the data were processed

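Polyadenylated RNA was sequenced from RAW246.7 cells, the submitters' spelling of a mouse macrophage-like line, under what the labels call normal strain loading (control) or under 20% elongation strain (stretched), both for 24 h. The labels give no strain value for the normal condition and do not say whether it means no applied strain or a lower one, nor whether the strain was cyclic or static, so each difference is between 20% strain and that condition. There was 1 library per group. Per the labels' protocols, RNA was extracted with TRIzol, selected for poly(A) tails and made into strand-marked libraries by the dUTP method. The labels also name the tissue as synovial membrane, while the cell line they name is a cultured line, and the description here follows the cell line. Columns marked as control in the deposited tables were assigned to the sample with the normal condition (titled NC), and columns marked as tensile to the loaded sample.

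The submitters' processing notes name StringTie and the genome build GRCm39. The aligner, the tool versions and the strand setting of the counting are not given in the sources used here. The deposited gene table gives, per the file headers, an estimated count and an FPKM value (fragments per kilobase of transcript, scaled to depth) for 55414 genes, and a second deposited table gives the same estimated counts and FPKM for 142438 transcripts with their transcript length in bases. A further table by the authors holds, for the 23250 genes with at least 1 count, a log2 fold change, a p-value and an adjusted p-value per the file headers. Of the deposited mapping summary, the total read count per the file headers was used, which stood there for the stretched library and was 35454910 reads. Values of 4 further deposited tables repeat rows of that table and were not used here.

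The estimated counts were checked against the other deposited columns. For 99.4% of transcripts with a value in the control library and 99.5% in the stretched library, the count lay within 0.05 of the interval between FPKM times length times 1 constant per library and that product plus 1, so the authors' counts are coverage estimates rounded up per transcript. The gene count equalled the sum of its transcripts for 32700 of 32704 genes whose transcripts carry a gene identifier; 26337 transcripts carry none. Rounding up raises low counts, and estimated counts of overlapping gene models depend on how coverage was divided between them. The authors' p-values were checked with edgeR's exact test on the gene counts after TMM scaling with an assumed biological coefficient of variation of 0.1: 100% of the 23250 p-values lay within 0.05 on the log10 scale. That test takes the variation between cultures as given and does not measure it.

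Here the gene counts were scaled by edgeR 4.0.16 TMM factors in R 4.3.3 (0.995 for control and 1.01 for stretched). The log2 difference is the log2 ratio of counts divided by the scaled library total, stretched over control, with a prior of 0.5 counts. Each ratio has an exact conditional binomial 95% interval. The intervals, and the floor of 3 counts used where a library had 0, cover counting error only, since PCR copies without molecular identifiers are not independent molecules and 1 library per group has no measure of variation between cultures. A gene met the size rule when it had at least 20 counts over both libraries, differed by at least 2-fold and had an interval that excluded 1. The exact test was run only to check the authors' p-values and, after the data were seen, to count their calls under other assumed variations; no p-value of it is given for a gene here. A gene with counts in the stretched library alone was given as a ratio to the floor, which leaves out counting error in the stretched library.

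A total of 44 gene lists, 9 of them cell type markers, were written before the data were examined. Of their 1218 entries, 1201 matched a gene symbol, 15 a synonym in the deposited table and 2 neither. Symbols came from the deposited table for 32704 genes and from the GENCODE name table, by gene identifier, for 20334 more; 2376 genes stayed without a name. That reference is of another build, GRCm38, so it was used for names alone and all coordinates are those of the deposited tables (GRCm39). Where a symbol belonged to several identifiers, the one with the highest count was used. For each list with at least 5 members past the count filter, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 libraries and is no test of the treatment. A list is said to lie outside the random lists at or above the 97.5th percentile or at or below the 2.5th. Genes named in the text were chosen by a rule written beforehand: Rapgef3 and Rapgef4; the 12 largest higher and the 12 largest lower differences among genes that are not predicted models and reach 5 FPKM in at least 1 library; up to 4 members of each list with the largest difference in size; and the 2 members of each marker list with the highest level. Genes outside this rule are named as such, and some genes the rule selects are not reported here.

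The procedure was tested on simulated libraries with the means and depths of these 2, with 200 genes changed. With counting noise alone, 96% of genes changed 3-fold and 95% of those changed 6-fold met the size rule, together with 44 of 12583 unchanged genes. When an unmeasured coefficient of variation between cultures of 0.1 was assumed, 66 of 12564 unchanged genes met it, with 0.2, 394 of 12556, and with 0.4, 3030 of 12535. For 40 simulated lists of 30 genes, a fixed shift of 1.5-fold was added to the computed log2 differences, with the counts left as they were. Of these lists, 40 lay above the random lists with an assumed variation of 0.2 and 32 with 0.4. Smaller shifts were not simulated, so recovery of lists with smaller medians was not measured. A further 40 lists of 30 genes were drawn at random from all simulated genes past the count filter, the changed ones included. Of these, 1 lay outside the random lists with counting noise alone, 4 with an assumed variation of 0.1, 2 with 0.2 and 1 with 0.4. They came from the same genes as the random lists, so a small share outside was set in advance by the percentile limits. Genes varied independently in these simulations, so genes of 1 list did not change together as they may between cultures. These counts are therefore no false rate for the gene lists used here. Alternatives covered the scaling (library totals, DESeq2 1.42.0 size factors), the prior (0.1 and 5), the count filter (none, 100 counts), the unit (FPKM, on the scale log2 of the value plus 1), the gene set, transcript sums, the fold threshold (1.5 and 4) and the form of the list comparison. Differential expression with replicates was not run, because the tables hold 1 column per sample. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.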

Results

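The series compared gene expression in mouse RAW246.7 macrophage-like cells after 24 h under a strain the labels call normal, with no value given (control), and after 24 h under 20% elongation (stretched), to find genes that respond to excessive mechanical load in a study centred on Rapgef3 in synovitis and osteoarthritis. Each group had 1 library and there were no replicates, so every difference below is between these 2 libraries and none could be set against the spread between cultures. The control library held 14769100 estimated counts and the stretched library 13391645. Counts above 0 were listed for 20388 genes in control and 20775 in stretched, and 12772 genes had at least 20 counts over both. The 10 most abundant genes took 6.83% of counts in control and 6.24% in stretched, and the median log2 difference over the 12772 genes was -0.0014.

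Rapgef3, which encodes a guanine nucleotide exchange factor for Rap proteins that is activated directly by cAMP (also called Epac1), was close to the detection limit in both libraries. The gene (ENSMUSG00000022469, chromosome 15, 97642651 to 97665853 on the minus strand, GRCm39) had 0 counts in control and 10 in stretched, 9 of them assigned to 1 protein-coding transcript and 1 to another, out of 17 annotated transcripts. Its level was 0.224 FPKM in the stretched library and was listed at 0 in control. Against the floor of 3 counts in control the gene was 3.64-fold higher in stretched, a ratio that leaves out counting error in the 10 counts. The lower 95% counting limit was 2.45-fold, a weaker bound. Its total was under the filter of 20 counts, so it is not among the genes counted below. The authors' deposited table lists Rapgef3 as higher, with a log2 fold change of 6.40, an unadjusted p of 0.00242 and an adjusted p of 0.090. Rapgef4, the related exchange factor Epac2, had 0 counts in control and 2 in stretched, too few for a comparison. Of 34 measured genes of Epac and cAMP signalling, 2 were higher, 1 was lower and 31 did not meet the size rule; the list's median of -0.02 lay at percentile 37.9 of random lists. Prkar2b, a regulatory subunit of protein kinase A, was 2.91-fold higher (33 and 89 counts, control and stretched; a log2 difference of 0.59 on the FPKM scale) and the adenosine receptor gene Adora2b 2.07-fold higher (55 and 105; 0.81 on that scale), whereas Rgs2, a regulator of G protein signalling, was 2.26-fold lower (1910 and 773). The orphan nuclear receptor gene Nr4a2 had a log2 difference of 0.97 and did not meet the rule.

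Across the transcriptome, 398 genes (3.12% of 12772) were at least 2-fold higher in the stretched library and 248 (1.94%) at least 2-fold lower, with counting intervals that excluded no difference. In simulated libraries of the same depth, 66 of 12564 unchanged genes met this rule when a coefficient of variation between cultures of 0.1 was assumed, 394 of 12556 with 0.2 and 3030 of 12535 with 0.4; the variation itself was not measured. Of the 36 gene lists with enough members, 14 had medians above and 5 below the random lists. Among named genes with at least 5 FPKM in 1 of the libraries, the 12 largest higher differences included interferon-stimulated and inflammatory genes. Ifi44l (ENSMUSG00000039146, chromosome 3, 151464374 to 151468529) had 33 counts in control and 476 in stretched, a log2 difference of 3.96 (95% counting interval 3.47 to 4.53). Oasl2 followed at 3.88, Apol9b at 3.83, Ifi202b at 3.41, Irf7 (chromosome 7, 140842619 to 140846394) at 3.24, the chemokine genes Cxcl10 and Ccl5 at 3.12 and 3.04, Usp18, which removes ISG15 from proteins, at 2.89, and Acod1, the enzyme that makes itaconate, at 2.86. Atp6v0d2, a proton pump subunit abundant in osteoclasts, had 16 and 186 counts and a log2 difference of 3.62. The 12 largest lower differences under the same limit of 5 FPKM included the hypoxia-responsive genes Ankrd37 (-1.87) and Bnip3 (-1.82), the cholesterol exporter gene Abcg1 (-1.53), Tmem176a (-1.66), the leukocyte actin-binding gene Lsp1 (-1.57), Selenbp1 (-1.52), the mitochondrial transfer RNA gene mt-Tk (-2.03, 33 and 7 counts) and the immunoglobulin heavy chain gene Ighm with 6422 counts in control and 2048 in stretched (-1.52). The joining segments Ighj2, Ighj3 and Ighj4 were lower as well, with differences between -1.90 and -2.06 on at most 34 counts. On the FPKM scale, where 1 is added to the value before the log2, differences of genes at low levels are smaller, and of the genes chosen by the naming rule these, given in the text as higher or lower, were under 2-fold there: Mfap3, Prkar2b, Adora2b, Socs1, Ccr1, Mx1, Kcnk2, Adgre5, Trpv4, Ptpn14, Ajuba, Gadd45a, Tagln, Abca1, Fabp4, Fas, Plk2, H1f4, Id1, Hbegf and Csf1.

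**Figure D1:**
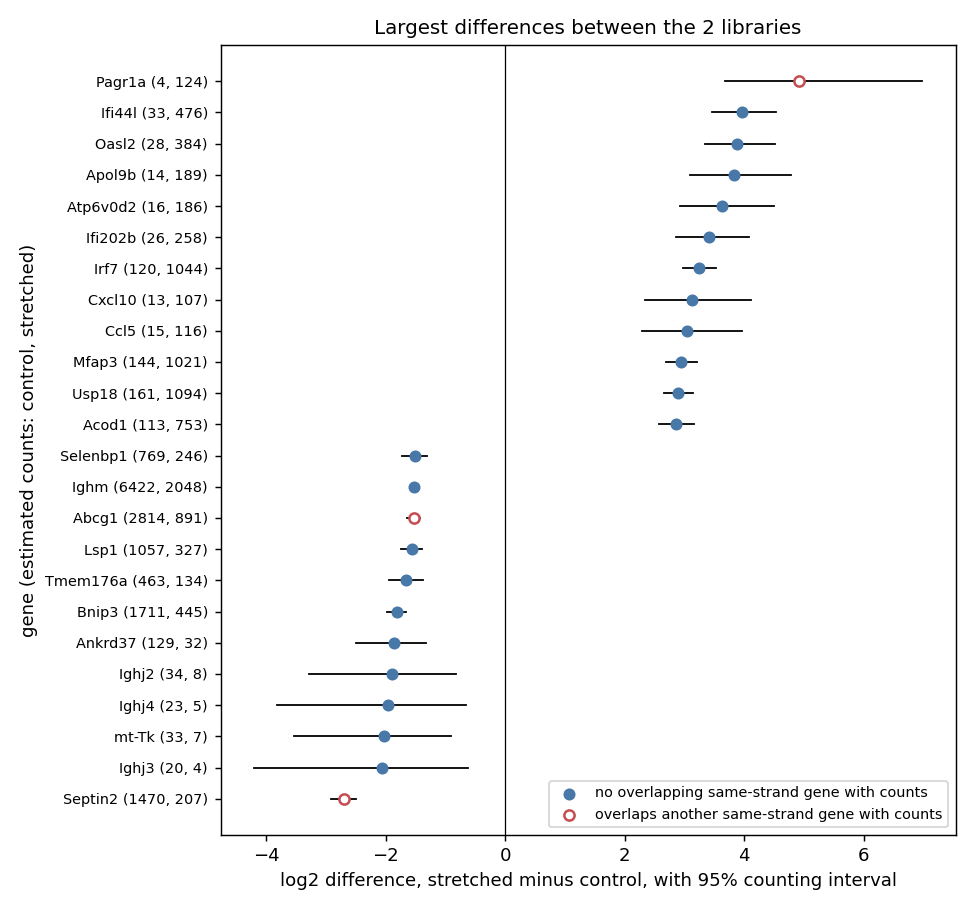
Log2 difference (stretched minus control, x axis) of the 12 genes with the largest higher and the 12 with the largest lower difference among named genes of at least 5 FPKM; bars are 95% counting intervals, numbers beside the names are estimated counts in control and stretched, and open circles mark genes that overlap another same-strand gene with counts. Differences reached 4.92 (Pagr1a, overlapping) on the higher side and -2.70 (Septin2, overlapping) on the lower side, and the intervals are widest for genes with few counts, such as Ighj3.

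Pagr1a, Septin2 and Mfap3, among these 24 genes, are uncertain because counts depend on the gene model. Pagr1a (ENSMUSG00000030680, chromosome 7, 126614205 to 126616524) had 4 and 124 counts, a log2 difference of 4.92, but it overlaps a second model of the same name, and the log2 difference of the summed counts of the overlapping models was -0.01. Septin2 (ENSMUSG00000026276, chromosome 1, 93406686 to 93437982), with 1470 and 207 counts, overlaps a model named Sept2 with 2657 and 3985, and their summed counts differed by 0.15. Mfap3 had 144 and 1021 counts, of which 0 and 952 were assigned to its longest transcript of 4839 bases, while its FPKM was 12.2 and 19.7. Of the 646 genes that met the size rule, 171 overlapped another same-strand gene with counts, and for 112 of these the locus sum differed by less than 1.5-fold. Irf7, Ankrd37, Tmem176a and Lsp1 also overlap an expressed gene on the opposite strand; the kit marks strand, but whether the counting used it is not given in the sources used here.

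Interferon-stimulated genes formed the list farthest above the random lists. Of 45 measured genes, 32 were higher, 0 lower and 13 did not meet the rule, and all 45 had a log2 difference above 0. The list's median was 1.32 (percentile 100 of random lists, whose central 95% ran from -0.10 to 0.12). Beside Ifi44l, Oasl2 and Irf7, Mx1, annotated in the deposited table as a polymorphic pseudogene, was higher with 3 and 29 counts. It differed 9.20-fold, with a 95% counting interval on the log2 scale of 1.71 to 5.76. On the FPKM scale its log2 difference was 0.67, under 2-fold. The summed counts of the 45 genes were 23939 in control and 47808 in stretched.

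Genes of classical (M1-type) macrophage activation were higher in part. Of 16 measured, 7 were higher, 0 lower and 9 met neither side, with a median of 0.73 (percentile 100). In the interferon list, 1 member also occurs, and the median without it was 0.56. That removal follows list membership alone and does not separate this list from a response to interferon. Beside Cxcl10, Ccl5 and Acod1, the interleukin 23 subunit gene Il23a was 3.94-fold higher (11 and 41 counts). Of 12 measured chemokine and receptor genes, 5 were higher and 0 lower, with a median of 0.92 (percentile 100). Cxcl10 and Ccl5 are members of this list too, so the 2 results are not separate. Cxcl2 was 3.35-fold higher (387 and 1190) and Ccr1 3.73-fold (9 and 32). Of 16 genes of alternative (M2-type) activation, 4 were higher and 0 lower, and the median of 0.18 lay inside the random lists (percentile 93.1), while the mean of 0.52 lay outside (99.8) and the median of the 13 members with at least 100 counts was -0.073 (percentile 20.0). The higher members were Il1rn, the interleukin 1 receptor antagonist (7.14-fold, 107 and 703), the scavenger receptor gene Msr1 (3.43-fold, 341 and 1072), Myc (4.89-fold, 17 and 78) and Socs1 (2.89-fold, 8 and 22), which is also known as an interferon-inducible feedback inhibitor. The 33 measured genes of the NF-kB pathway and its targets had a median of 0.03 (percentile 74.5), with 1 higher (Ier3, 2.29-fold), 0 lower and 32 meeting neither. Bcl2a1b and Bcl2a1d, which are near-identical paralogs and therefore uncertain, had differences of -0.87 and -0.55, and Plaur 0.59. Of 15 inflammasome and pyroptosis genes, 1 was higher, Txnip (2.01-fold, 7095 and 13093; under 2-fold with DESeq2 size factors, at a log2 difference of 0.97), and the median was -0.01 (percentile 49.9); Nlrc4, Ninj1 and Il18 had differences of 0.75, 0.63 and 0.40.

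Phagocytosis and surface receptor genes had a median of 0.26 (percentile 100), with 7 of 30 higher and 0 lower. Itgax, encoding integrin CD11c, was 7.72-fold higher (13 and 95 counts), the sialoadhesin gene Siglec1 4.18-fold (85 and 327) and the Fc receptor gene Fcgr4 3.62-fold (15 and 51). In the osteoclast differentiation list, Atp6v0d2 was higher and Fos lower (2.75-fold, 770 and 256) among 21 genes, and the median was 0.16 (percentile 99.3, or 97.4 with counts rebuilt without rounding up); Acp5 and Tcirg1 had differences of 0.95 and 0.80. Of 15 matrix proteases and inhibitors, 0 met the rule in either direction, with a median of 0.26 (percentile 99.7; the mean lay inside the random lists at 97.1) and the largest values at Adam8 (0.81), Ctsl (0.79), Adamts1 (0.51) and Ctsd (0.47). Growth factors and cytokines of repair had 5 higher and 0 lower among 13, with a median of 0.58 (percentile 100), or 1.26 over 18 members with no count filter. Spp1, encoding osteopontin (chromosome 5, 104582984 to 104588916), had 23778 and 72572 counts and was 3.33-fold higher (log2 interval 1.71 to 1.76). Hbegf was 7.64-fold higher on 5 and 38 counts, Gdf15 2.75-fold (31 and 79) and Csf1 2.55-fold (13 and 31).

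**Figure D2:**
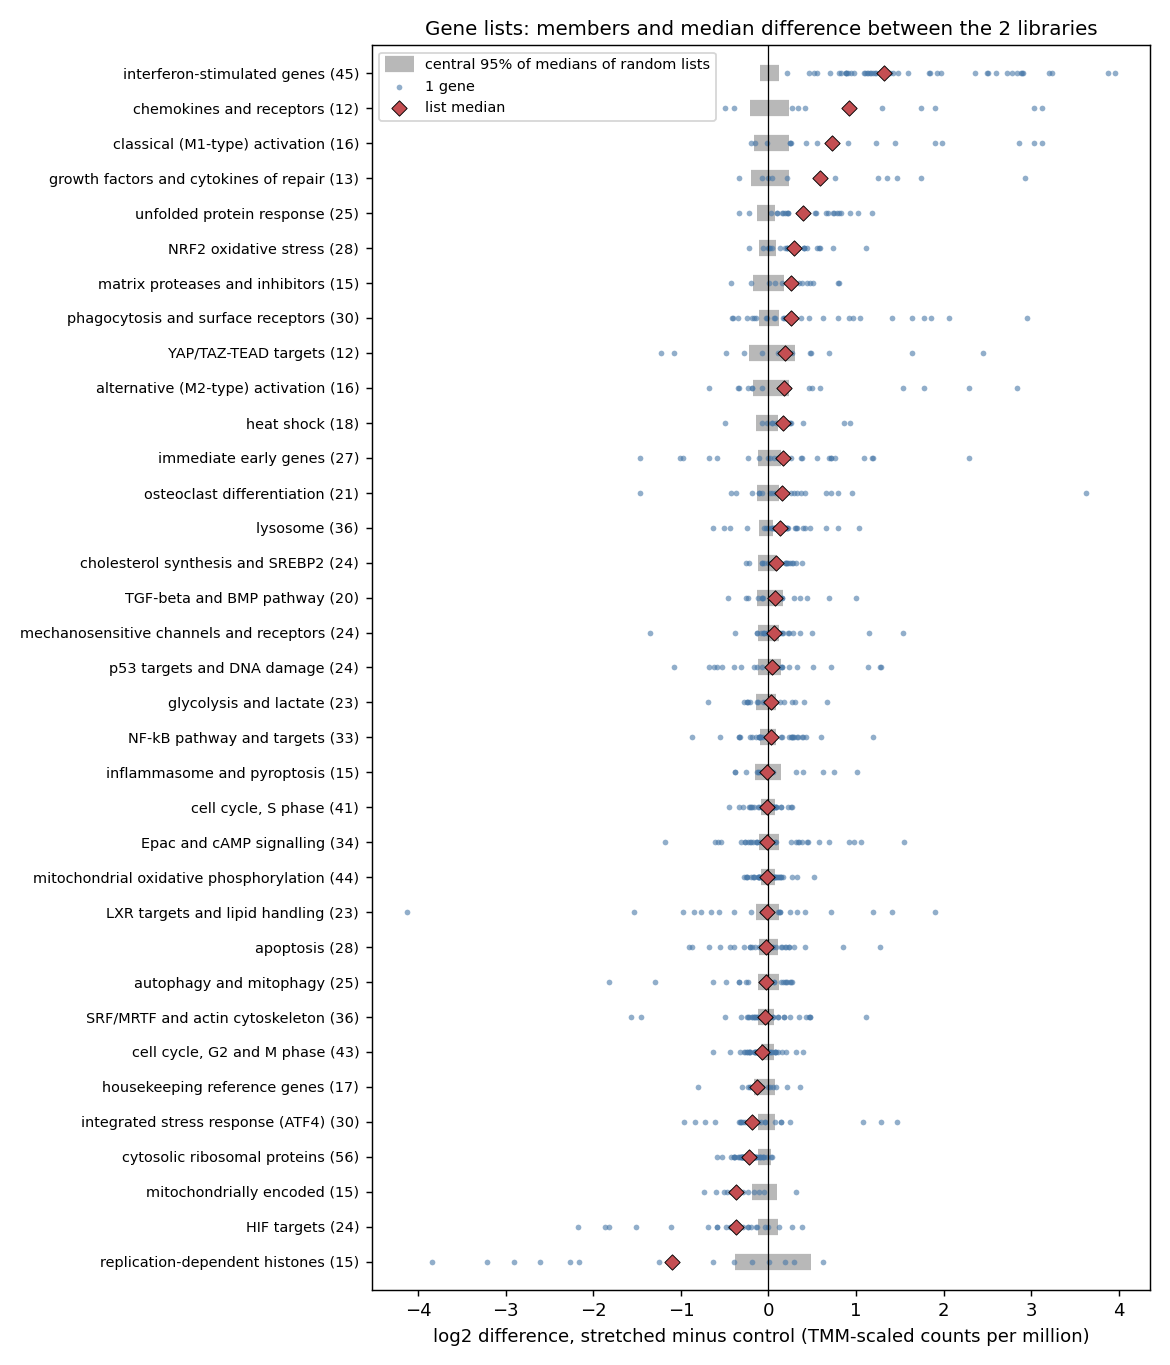
Log2 difference (stretched minus control, x axis) of each measured member of the 35 gene lists other than cell type markers (blue points), the list median (red diamond) and the central 95% of medians of 10000 random lists matched on expression (grey bar); numbers in brackets are measured members, and H2ac20, at 0 counts in stretched, is drawn at its bound. The median of the interferon-stimulated genes lies at 1.32, that of the HIF targets at -0.37 and that of the replication-dependent histones at -1.10.

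Of the lists tied to mechanical signalling, the immediate early genes had a median above the random lists and the others had medians inside them. Of 24 mechanosensitive channels and receptors, 2 were higher, 1 lower and 21 neither, with a median of 0.06 (percentile 82.4). The cation channel gene Trpv4 was 2.21-fold higher (51 and 104 counts), the potassium channel gene Kcnk2 2.89-fold higher (11 and 30) and Adgre5 2.55-fold lower (51 and 18), while Itga5 had a difference of 0.50. Piezo1, outside the naming rule and added after its values were seen, had 2721 and 3024 counts (0.28). Of 12 YAP/TAZ-TEAD targets, 2 were higher (Ptpn14, 5 and 27 counts, and Axl, 57 and 163) and 2 lower (Ajuba, 62 and 24, and Gadd45a, 56 and 24), with a median of 0.19 (percentile 89.4, or 99.7 for the 6 members with at least 100 counts). Of 36 SRF/MRTF and actin cytoskeleton genes, 1 was higher (Actn1, 2.16-fold) and 2 lower (Lsp1, and Tagln on 25 and 8 counts), with a median of -0.04 (percentile 39.0); Actg1 had a difference of -0.49. Of 27 immediate early genes, 4 were higher and 2 lower, with a median of 0.17 (percentile 99.0; the mean lay just inside the random lists). Myc, Ier3 and Dusp4 (2.28-fold, 727 and 1517) were higher and Fos was lower. The other lower member was Fosb, outside the naming rule, which no longer met the size rule with scaling by library totals. Egr1, also outside the naming rule, met the size rule on the lower side with DESeq2 size factors but not in the main setting. The raised median therefore does not describe Fos, Fosb and Egr1. The 20 genes of the TGF-beta and BMP pathway had a median of 0.07 (percentile 81.1) and 1 higher member, Id1, on 15 and 28 counts, which was under 2-fold with DESeq2 size factors (a log2 difference of 0.96), with unrounded counts and with a prior of 5; Smad7 and Smad3 had differences of 0.69 and -0.47.

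Genes of the unfolded protein response were higher as a group. The median over 25 genes was 0.40 (percentile 100), 23 of them had differences above 0, and 2 met the rule: Hspa5, the chaperone BiP of the endoplasmic reticulum (chromosome 2, 34661982 to 34667559), with 14563 and 30287 counts (2.27-fold, log2 interval 1.15 to 1.21), and its cofactor gene Sdf2l1 (2.02-fold, but a log2 difference of 0.97 with DESeq2 size factors). Pdia6 and Hyou1 had differences of 0.93 and 0.83. The integrated stress response list had a median of -0.19 (percentile 0.02) over 30 genes, although its 3 members that met the rule, Gdf15, Chac1 (2.44-fold) and Ddit3 (2.11-fold), were higher; Trib3 had a difference of -0.97. Its mean of -0.08 lay inside the random lists (percentile 6.98). The NRF2 oxidative stress list had a median of 0.29 (percentile 100) over 28 genes and 1 higher member, Gstm1 (2.16-fold), with Ftl1 at 0.73, Hmox1 at 0.58 and Srxn1 at 0.58. Heat shock genes had a median of 0.17 (percentile 99.7) and 0 of 18 met the rule; Hsph1, Hspa1b, Dnajb1 and Hspa4l had differences of 0.94, 0.86, -0.50 and 0.39. Of 24 p53 target and DNA damage genes, Gadd45b (2.43-fold), Fas (2.42-fold, 11 and 25 counts) and Plk2 (2.20-fold) were higher and Gadd45a lower, with a median of 0.05 (percentile 73.2). Of 28 apoptosis genes, 1 was higher (Fas), with a median of -0.02 (percentile 35.5); Bcl2a1a and Tnfrsf1b had differences of -0.90 and 0.85.

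Targets of the hypoxia-inducible factor HIF were lower as a group. Of 24, 5 were lower, 0 higher and 19 neither, and the median was -0.37 (percentile 0). Adm, encoding adrenomedullin, was 4.52-fold lower (76 and 15 counts), Ankrd37 3.65-fold (129 and 32), Bnip3 (chromosome 7, 138492565 to 138511248), a mitophagy receptor, 3.52-fold (1711 and 445) and Selenbp1 2.86-fold (769 and 246). The fifth, Ero1a, was outside the naming rule and is named because the count is small (7032 and 2989). Glycolysis and lactate genes, many of them also HIF-responsive, had a median of 0.03 (percentile 84.7) and 0 of 23 met the rule; Pdk1, Hk3, Eno2 and Hk1 had differences of -0.70, 0.67, 0.40 and 0.30. Nuclear-encoded oxidative phosphorylation genes had a median of -0.02 (percentile 38.6) with 0 of 44 meeting the rule, and differences of 0.52 at Cox8a, 0.33 at Ndufa8, -0.28 at Uqcrc2 and 0.27 at Ndufb3. Mitochondrially encoded genes had a median of -0.37 (percentile 0) with 0 of 15 meeting the rule; mt-Atp8, whose model overlaps mt-Atp6, had a difference of -0.73, mt-Cytb -0.60, mt-Atp6 -0.50 and mt-Nd3 -0.48. The mitochondrial genome took 4.98% of counts in control (Wilson 95% interval 4.97% to 4.99%) and 4.02% in stretched (4.01% to 4.03%). Cytosolic ribosomal protein genes had a median of -0.23 (percentile 0), 54 of 56 below 0 and 0 meeting the rule, with Rpl35 at -0.59 by counts (but 352 and 356 FPKM), Rpl30 at -0.53, Rpl36 at -0.43 and Rps29 at -0.40. The 17 housekeeping reference genes had a median of -0.13 (percentile 7.71); Tfrc was at 0.35, Eef1a1 at -0.30 and Eef2 at -0.23.

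The list of LXR targets and lipid handling had 3 higher and 2 lower of 23 genes and a median of -0.02 (percentile 44.9). Its mean of -0.15 lay just inside the random lists (percentile 2.88). Abca1 (chromosome 4, 53030787 to 53159895), a cholesterol exporter, had 85 counts in control and 4 in stretched (17.4-fold lower, log2 interval -6.19 to -2.87; a log2 difference of -0.55 on the FPKM scale, under 2-fold), and Abcg1, with the same known function, 2814 and 891 (2.89-fold lower). Fabp4 (9 and 32 counts) and the fatty acid receptor gene Cd36 (93 and 228) were higher. Cholesterol synthesis and SREBP2 genes had a median of 0.09 (percentile 97.6) with 0 of 24 meeting the rule; Acat2, Idi1 and Dhcr7 had differences of 0.38, 0.31 and 0.26. The percentile fell back inside the random lists under 7 of the alternatives. Of 36 lysosome genes, 1 was higher, Gpnmb (2.05-fold, 12818 and 24095; under 2-fold with DESeq2 size factors, at a log2 difference of 0.99), with a median of 0.13 (percentile 99.99); Neu1 had a difference of 0.65 and Tfeb of -0.64. Of 25 autophagy and mitophagy genes, 2 were lower, Bnip3 among them, with Bnip3l at -0.49 and a median of -0.03 (percentile 34.5), whereas the mean was -0.15 (percentile 1.39).

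The medians of both cell cycle lists lay inside the random lists. S phase genes had a median of -0.02 (percentile 41.7) and G2 and M phase genes of -0.07 (percentile 3.56), although the mean of the latter (-0.078) lay below the random lists (percentile 1.26); 0 of 41 and 0 of 43 met the rule. The largest differences were Slbp (-0.45), Rfc4 (-0.34), Rfc3 (-0.29) and Gins2 (0.26) in S phase, and Nusap1 (-0.64), Mad2l1 (-0.44), Cdc25b (0.39) and Kif11 (-0.32) in G2 and M. The replication-dependent histones, whose messenger RNAs mostly lack poly(A) tails, had a median of -1.10 (percentile 0), with 7 of 15 lower and 0 higher. Of the 15, 4 were above 0, among them H1f2 (190 and 213 counts, 0.29), H2bc4 (45 and 47, 0.19) and H4c9 (14 and 20, 0.63). The 7 lower members had at most 44 counts in control. H2ac20 had 20 counts in control and 0 in stretched, 6.11-fold lower against the floor of 3 counts. The 95% counting limit of its log2 ratio nearest to 0 was -2.18, a weaker bound. The list's median stayed at -1.10 with this gene at its ratio to the floor. H1f1 had 23 and 1 counts (log2 interval -9.76 to -1.78), H1f4 35 and 3 (-5.76 to -1.75) and H2bc11 20 and 2 (-6.34 to -1.15). These genes are short, close paralogs at low counts, and H1f4 overlaps H2bc6, so single values are uncertain. The list also holds H1f0, a replacement histone whose messenger RNA carries a tail, named after its values were seen, with 4179 and 3840 counts.

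Markers of other cell types were near the detection limit with few exceptions, and macrophage markers were abundant. Of 96 marker entries for 8 other cell types, 7 reached 1 FPKM in either library. Macrophage markers had a median of 0.13 over 17 genes (percentile 98.1, or 94.2 for the 15 with at least 100 counts), with Lyz2 at 1320 FPKM in control and 2289 in stretched and Cd14 at 445 and 569. Among synovial fibroblast markers, Vim, which macrophages also express, had 249 and 234 FPKM, and Prg4 0.172 and 0.124. The chondrocyte markers Comp and Matn3 had 0.788 and 0.790, and 0.112 and 0.195 FPKM. The endothelial markers Egfl7 and Eng had 9.92 and 4.04, and 2.05 and 2.18 FPKM. Of T and NK cell markers, Lck had 5.92 and 4.59 FPKM and Cd3e 0.0779 and 0.155; of B and plasma cell markers, Ighm had 237.6 and 86.6 FPKM and Cd79a 0.265 and 0.265. The neutrophil markers were Csf3r with 6.38 and 3.37 FPKM and Camp with 0 and 2 counts, the mast cell and basophil markers Hdc with 0.351 and 0.757 FPKM and Kit with 0 and 3 counts, and the dendritic cell markers Itgax with 0.168 and 1.78 FPKM and Zbtb46 with 0.764 and 0.302.

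The authors' deposited table calls 507 genes higher and 361 lower, which are all 868 genes with at least a 2-fold change and an unadjusted p under 0.05. In the authors' deposited table, 390 of them have an adjusted p under 0.05 (265 higher and 125 lower). The p-values in the authors' deposited table equal those of edgeR's exact test with an assumed coefficient of variation of 0.1 between cultures, which 1 library per group cannot measure. Of the 507 genes called higher in the authors' deposited table, 382 met the size rule here and 123 had fewer than 20 counts over both libraries; of the 361 called lower, 226 met it and 133 had fewer than 20. The genes called higher by the authors' deposited table include 62 with 0 counts in control, Rapgef3 among them. Those called lower include 82 with 0 counts in stretched.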

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

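The settings with counts rebuilt without rounding up, random lists from protein-coding genes, lists scaled by DESeq2 size factors, loci left out and other assumed variations were chosen after seeing the data, and the others before the data were examined. The counts of 398 higher and 248 lower genes stayed within 1.5 times under both other scalings, both priors, no filter and without loci whose sum differed by less than 1.5-fold (358 and 176). A 1.5-fold threshold gave 792 and 465 and a 4-fold threshold 88 and 55; a filter at 100 counts gave 182 and 66, and FPKM 178 and 104. The lower genes numbered 155 of 11203 protein-coding genes, 155 of 11661 genes with transcript sums and 152 of 11560 with unrounded counts. These settings tested fewer genes than the 12772 of the main setting. Of the lower genes with transcript sums, 154 were among the 248, and of those with unrounded counts 146. The higher share of calls was 61.6%, and 57.9% to 63.1% under the other scalings. No gene called in one direction was called in the other. The fitted log2 difference of Rapgef3 depends on the prior (4.52 with 0.5, 6.78 with 0.1, 1.71 with 5) and was 0.29 on the FPKM scale, whose added 1 exceeds its level. Its log2 ratio to the floor, 1.86, moved between 1.76 and 1.88, without counting error in its 10 counts. Of 155 other named genes, 101 stayed within their counting interval under every setting. Of the 76 that met the size rule, 0 changed sign, but 4 were under 2-fold with DESeq2 size factors (Gpnmb, Sdf2l1, Txnip and Id1), 3 with a prior of 5 and 23 on the FPKM scale. Of those that did not meet it, 3 changed sign on the FPKM scale (Rpl35, Comp and Cd79a), Cd79a also with a prior of 5.

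Of 36 list percentiles, 19 lay outside the random lists, and 16 to 19 under the alternatives; the mitochondrially encoded list had too few members with transcript sums (17 of 35 lists outside) and unrounded counts (16 of 35), and the histones at 100 counts (17 of 35), so 1 list in each was not run rather than lost. Taking the mean brought in alternative activation (0.52), G2 and M phase (-0.078) and autophagy (-0.15) and put out matrix proteases (0.27), immediate early genes (0.22), the integrated stress response (-0.083) and cholesterol synthesis (0.097). Cholesterol synthesis also fell inside with no filter (0.094), a filter at 100 counts, unmatched random lists and protein-coding genes (0.091 each), transcript sums (0.083) and unrounded counts (0.085). Osteoclast differentiation fell inside with unrounded counts (0.12) and macrophage markers with a filter at 100 counts (0.072) and unmatched lists (0.13), while YAP/TAZ-TEAD targets moved outside at 100 counts (0.37). The median of alternative activation was -0.073 at 100 counts and that of repair genes 1.26 with no filter. With DESeq2 size factors 0 members were called in the inflammasome, lysosome and TGF-beta lists, 1 in the unfolded protein response, and 1 more lower member each in the immediate early, LXR and integrated stress lists; with library totals 1 lower member fewer in the immediate early and histone lists. The cause was not tested. The authors' calls came to 77 higher and 41 lower at an adjusted p under 0.01 and 4-fold, and to 4333 and 3381 by 2-fold size alone; their test with an assumed variation of 0.2 gave 433 and 303, and with 0.4, 156 and 113. With 10 counts for Rapgef3, depth does not fix the size of its difference.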

Other observations

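Genes outside the lists, named here after their values were seen, included the long noncoding RNA Neat1, which builds nuclear paraspeckles, with 2934 counts in control and 13406 in stretched (log2 difference 2.32, 95% counting interval 2.26 to 2.38), whereas its neighbour Malat1 had 7761 and 7946 (0.16). Higher genes also included H2-T24 (170 and 1052 counts, 2.75) and H2-T23 (359 and 1077, 1.71), which belong to a family of close paralogs and are uncertain, the galectin gene Lgals9 (160 and 737, 2.33), Lgals3bp (1354 and 2826, 1.19), the aminopeptidase gene Anpep (327 and 1014, 1.76), and the RNA helicase genes Helz2 (943 and 2364, 1.45) and Mov10 (368 and 822, 1.28). Hdac9 was lower (994 and 355, -1.36), as was Tmem176b (1405 and 507, -1.34), the partner gene of Tmem176a. Interferons themselves were near 0: the 21 type I, II and III interferon genes in the table summed to 2 counts in control and 3 in stretched. Of the components that signal for them, Stat2 was higher (380 and 778, 1.16) and Irf9 had a difference of 0.80, while the receptor gene Ifnar2 had 1372 and 794 counts (-0.66).

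In the 3 patterns below, the tests were chosen after the result was seen, except the one matched on transcript length. The first pattern is the higher level of interferon-stimulated genes. A trend with transcript length or expression level is argued against, since the list's median lay at percentile 100 among random lists matched on both. For RNA of another cell type in the stretched library, markers of 8 other types differed by -350.5 CPM in sum (stretched minus control), mostly Ighm. The interferon-stimulated genes gained 1921. The fall of Ighm could hide gains of other markers, so the sum cannot decide. Of the 8 lists, 2 gained, the largest gain being 4.02, so no large gain was seen for these types. Cell types outside these lists were not covered. A difference between the cultures or libraries unrelated to stretch cannot be told apart from an effect of stretch, because there was 1 library per group. An effect of stretch stays open and was not tested.

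The second pattern is the low median of replication-dependent histones in the stretched library, although 4 of the 15 members were above 0. A smaller share of cells in S phase that lowers both lists alike is argued against. The median of the S phase list was -0.017 (quartiles -0.08 and 0.06) and that of the histones -1.10. A smaller fall in that share is not excluded, because how far each list changes with it was not measured. Less carry-over of RNA without poly(A) tails may account for part of it: the median of 15 small nuclear, small nucleolar, ribosomal and other noncoding RNA genes was -0.45 (quartiles -1.40 and -0.18). The 18S ribosomal RNA gene Rn18s-rs5, 1 of the 15, had 9072 and 8192 counts and a difference of -0.02 (interval -0.06 to 0.02), so the tables do not decide. An effect of stretch on histone messenger RNA was not tested.

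The third pattern is the calls at overlapping gene models. Estimated counts that moved between overlapping same-strand models may account for some of them: 31 of the 171 overlapping calls had a partner with an opposite count difference of 0.5 to 2 times the size, but 22 had one in the same direction, so this stays undecided for the set. Such movement is argued against as the source of most calls, since 475 of the 646 had no overlapping same-strand gene with counts. No biological explanation was tested.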
